A study of Mus musculus with 9 samples.

How the data were processed

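CUT&Tag was run on mouse periosteal stem and progenitor cells, per the labels. The cells were cultured in osteogenic medium with 50 µg/ml ascorbic acid, 5 mM beta-glycerophosphate and 1e-07 M dexamethasone for 3 days. Lentivirus was used at a multiplicity of 10 for all but the H3K4me3 library, whose treatment label names none. Groups were taken from the sample titles: PLAGL1-HA (n = 1), IgG (n = 1), H3K4me3 (n = 1), KLF4-FLAG in Plagl1fl/fl cells (n = 3) and KLF4-FLAG in Ctsk-iCre;Plagl1fl/fl cells (n = 3). The vector names in the treatment labels of the 6 KLF4 libraries run from Klf4 to Klf9, while the titles and the description of the construct name Klf4 throughout, and the titles were followed. The labels do not say whether replicates came from separate animals, so p-values of the comparison of control and Plagl1-deficient cells measure only the spread between these samples, which may be technical.

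The submitters' processing notes name Trim Galore 0.6.10, Bowtie2 2.5.4, GATK 4.5.5.0, SAMtools 1.21, deepTools 3.5.5, MACS3 3.0.2, DiffBind 3.16.0, edgeR 4.2.0 and HOMER 4.11.1, with no role or order, and the build mm39. How duplicates, reads with several matches and spike-in or library scaling were handled is not given in the sources used here. The PLAGL1 peaks were called on the HA library against the IgG library, and each carries the authors' peak score, whole numbers from 20 in the deposited file. The H3K4me3 list has the same kind of deposited score from 1 library, and whether a control library was used is not given in the sources used here. A score is the authors' own value of a peak and was used only to describe, rank or filter peaks within its list. The distance to the TSS in base pairs, the annotation class and the gene name of each peak are those of the authors' annotation, per the file headers.

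For KLF4, the authors' deposited table holds 1 row per consensus site with a log2 fold change, a mean log2 CPM, an F score, a p-value and an adjusted p-value. Its name credits edgeR with the comparison, per the file name of the authors. The deposited adjusted p-value equals the Benjamini-Hochberg adjustment of the deposited p-value over all sites. The table has no values per library, so the counts were not refitted, totals per library are unknown, and the design's provision for such a table was followed: the authors' calls at an adjusted p under 0.05 were used. Which group is the numerator of the log2 fold change is not stated in the deposited table, so "lower" and "higher in the knockout" could not be assigned and signs are given instead. Scaling between libraries matters here, since it sets where 0 lies for every site. The deposited files have 0 columns of values from further samples.

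From these files the following was computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plotted with matplotlib 3.10.9. An approximate standard error was taken as the absolute log2 fold change divided by the square root of F, and the 95% interval from the degrees of freedom solved from F and the p-value (median 87.6; used where F was under 0.5 or no solution was found). KLF4 sites have no gene name in the table. Each took the gene of the H3K4me3 peak it overlapped most, otherwise of the PLAGL1 peak, otherwise of the nearest peak within 3 kb of a TSS at most 100 kb away, which named 89.6% of sites. Overlap meant at least 1 bp. Shares have Wilson 95% intervals, which cover counting error only. Fisher's exact tests were two-sided. Stratified tests were exact and conditional, with the Mantel-Haenszel odds ratio. They replaced the Cochran-Mantel-Haenszel test of the design, whose normal approximation is poor for 8 called sites, after the data were seen. KLF4 sites were stratified by 3 equal groups of mean signal and, for PLAGL1, by H3K4me3 overlap, which stood in for the promoter class of the design because the KLF4 table has no annotation. PLAGL1 peaks were placed at random 1000 times on their own chromosomes. Enrichment of a list among marked genes used the H3K4me3-marked genes as background. The difference in mean log2 fold change between classes of sites was tested by an exact sign-flip test over the 19 autosomes, which takes chromosomes of the same 6 libraries as units and so does not measure the spread between samples.

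Symbols were matched to a RefSeq table of the assembly GRCm38.p6, used for names only: 98.1% of the gene names in the PLAGL1 list and 98.0% of those in the H3K4me3 list were found. On simulated data the sign-flip test gave a p under 0.05 in 5% of 100 runs without a shift and in 100% of runs with a shift of -0.2 in 200 of 20801 sites. These runs flagged sites at random with independent errors, so they check the calculation only. They do not give the error rate or power for the smaller differences reported here, at sites tied to signal. At the errors of the 21130 KLF4 sites, adjustment recovered 20.1% of 200 sites shifted by 0.5 and 78.6% of those shifted by 1.

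The 20 gene lists and the rule for named genes were fixed before the data were examined. The rule took every peak of Plagl1, Klf4 and Irx5, and the called KLF4 sites with a gene name that is not a predicted gene. Among PLAGL1 peaks with such a name it took the 10 with the highest score. It also took up to 4 PLAGL1-bound genes and up to 3 H3K4me3-marked genes per list, and genes with both a PLAGL1 promoter peak and a called negative KLF4 site. The values of 3 genes that the rule picked are not reported here. Genes outside the rule are said to be so, as are sites chosen by their unadjusted p. Alternatives covered the threshold, the overlap, the score of the peaks and the distance to the TSS. Search for KLF and PLAGL1 motifs was left out because no genome of the build mm39 was at hand, and the promoter share of KLF4 sites because the table carries no annotation.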

Results

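The study profiled chromatin in mouse periosteal stem and progenitor cells, which line the bone surface and were taken here from the angle of the mandible at 8 weeks of age and held for 3 days in osteogenic medium. It used CUT&Tag, in which an antibody tethers a transposase to its target so that DNA fragments near the target are released and sequenced. The 9 libraries comprised 1 for HA-tagged PLAGL1, 1 for IgG from the same kind of cells, 1 for the promoter mark H3K4me3, and 6 for FLAG-tagged KLF4. PLAGL1 is an imprinted zinc-finger transcription factor, and KLF4 is a Krüppel-like zinc-finger factor. The tagged factors were supplied by lentivirus. Of the KLF4 libraries, 3 came from Plagl1fl/fl control cells and 3 from Ctsk-iCre;Plagl1fl/fl cells, in which the Cre driver deletes Plagl1. The series title sets the question as an axis from PLAGL1 through KLF4 to IRX5, an Iroquois homeobox factor. PLAGL1 was represented by 3463 peaks with a median width of 188 bp, H3K4me3 by 16251 peaks with a median width of 1164 bp, and KLF4 by 21130 consensus sites, per the authors' deposited table. Sequencing depth per library is not given in the sources used here, and PLAGL1 and H3K4me3 had no replicates, so their values describe single libraries.

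The first comparison asked which genes carried the promoter mark in these cells. H3K4me3 peaks lay within 3 kb of the transcription start site (TSS) of 11226 of 21896 protein-coding genes, or 51.3%. Periosteal progenitor genes and craniofacial transcription factors were marked almost throughout. The periosteal and skeletal progenitor list had 20 of 21 genes marked, led by Itgav (peak score 1609), Pdgfrb (898) and Pdgfra (818), which encode an integrin subunit and 2 PDGF receptors, with Lepr as the exception. The craniofacial transcription factor list had 30 of 31 marked, with the highest scores at Dlx2 (1268), Tbx18 (901) and Twist1 (836). In contrast, only 7 of 39 HOX genes were marked, and their highest scores were low, at 225 for Hoxb4, 106 for Hoxa3 and 95 for Hoxa5. Against all protein-coding genes, Fisher's exact test with Benjamini-Hochberg adjustment over 20 lists gave adjusted p = 7.4e-07 for the craniofacial list, 0.00018 for the periosteal list and 0.00016 for the HOX list, the last for a deficit. The test of the periosteal list left out Mx1, which is not among the protein-coding symbols of the reference, and so compared 19 of 20 genes.

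The extracellular matrix list was marked at 28 of 30 genes (Itgb1 1315, Col6a2 1103, Itgb5 1097; adjusted p = 1.0e-05) and the BMP and TGF-beta list at 28 of 31 (Smad1 1472, Tgfbr2 1281, Smad5 1064; adjusted p = 3.7e-05). The WNT list had 26 of 30 genes marked (Axin1 1132, Fzd1 991, Dkk3 963; adjusted p = 0.00023), and the imprinted list 14 of 16 (Gnas 733, Ndn 440, Peg3 386; adjusted p = 0.0042 for 13 of 14, without H19 and Meg3, which are not protein-coding). The cell cycle and p53 list had 15 of 17 (Cdkn1b 1315, Mki67 1270, Mdm2 1241; adjusted p = 0.0049), and the housekeeping list 13 of 14 (Sdha 1897, B2m 1158, Gapdh 1094; adjusted p = 0.0042). The osteoblast list had 16 of 24 marked (adjusted p = 0.24), led by Sparc (840), Mef2c (836) and Atf4 (767). Its unmarked genes were Bglap, Bglap2, Dmp1, Ibsp, Ifitm5, Omd, Phex and Sost, which include markers of mature osteoblasts and osteocytes. Lists of other fates had 7 of 20 chondrocyte genes (Col11a1 801, Sox9 793, Wwp2 736; adjusted p = 0.24), 10 of 14 adipocyte genes (Cebpd 1153, Pparg 908, Lpl 667; adjusted p = 0.24) and 6 of 8 tendon genes (Mkx 645, Egr1 640, Dcn 139; adjusted p = 0.36, Fisher's exact test) marked. The KLF and SP list had 17 of 23 (Klf2 1292, Sp1 1177, Klf3 1109; adjusted p = 0.060) and the pluripotency list 3 of 14 (Myc 661, Tbx3 141, Mycn 61; adjusted p = 0.057, Fisher's exact test). In the Iroquois list Irx3 (700), Irx1 (470) and Irx5 (350) were marked and the other 3 members were not (adjusted p = 1, Fisher's exact test).

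Genes of other cell types also carried peaks. The macrophage and osteoclast list had 9 of 14 marked genes (adjusted p = 0.50, Fisher's exact test), with Tyrobp at 276, Spi1 at 253 and Fcer1g at 244. The endothelial list had 5 of 12 (Flt1 736, Kdr 179, Egfl7 159; adjusted p = 0.64, Fisher's exact test) and the Schwann cell and neuron list 5 of 10 (Erbb3 371, Mbp 314, Map2 221; adjusted p = 1, Fisher's exact test). None of the 10 skeletal muscle genes was marked (adjusted p = 0.0022, Fisher's exact test). The deposited annotation gives each peak to 1 gene, so a gene that shares its promoter with a neighbour can go unmarked. Plagl1 itself is such a case: no peak in any list bears its name, but an H3K4me3 peak at chr10:12966079-12967719 (mm39, score 487) was annotated to Hymai, a non-coding transcript of the same locus.

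The second comparison asked where tagged PLAGL1 was found. PLAGL1 peaks lay within 3 kb of the TSS of 1428 genes, of which 1228 (86.0%) were H3K4me3-marked. The family of KLF and SP factors stood out: 9 of its 17 marked genes had a PLAGL1 peak at the TSS, against 10.1% of all marked genes (odds ratio 10.1, adjusted p = 0.00024, Fisher's exact test over marked genes). The highest scores were at Klf9 (109, chr19:23118085-23118689), Klf6 (57, chr13:5911164-5911391), Sp2 (54) and Klf10 (49). Klf4 had no PLAGL1 peak near its TSS.

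Extracellular matrix genes were enriched as well, with 8 of 28 marked genes bound (odds ratio 3.57, adjusted p = 0.035, Fisher's exact test). They were led by the matrix metalloproteinases Mmp2 (score 57) and Mmp14 (55), fibronectin Fn1 (50) and the integrin subunit Itga5 (40). So were housekeeping genes, at 6 of 13 (odds ratio 7.66, adjusted p = 0.0097, Fisher's exact test), with B2m at 84, Polr2a at 70 and Gapdh at 65. Within strata of the H3K4me3 score, an exact stratified test gave adjusted p = 0.00049 for the KLF and SP list, 0.037 for the matrix list and 0.015 for the housekeeping list. The BMP and TGF-beta list had 7 of 28 (adjusted p = 0.094), at the BMP target Id1 (89), Id3 (47), Smad6 (35) and Id2 (31) among others. The craniofacial list had 6 of 30 (adjusted p = 0.47), among them Pbx3 (57), Tbx18 (50) and Barx1 (47).

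No periosteal progenitor gene had a PLAGL1 peak at its TSS among 20 marked (adjusted p = 0.61). The same count of 0 was found for 14 imprinted genes (adjusted p = 0.77), 10 adipocyte genes and 9 macrophage genes (both adjusted p = 0.79), and 5 endothelial and 5 Schwann cell or neuron genes (both adjusted p = 1, Fisher's exact test). Among osteoblast genes Col1a2 (30) and Alpl (21) were bound, 2 of 16 marked (adjusted p = 0.79, Fisher's exact test). Single marked members were bound in the WNT list (Tcf7l1, 72), the tendon list (Egr1, 153), the chondrocyte list (Comp, 39), the pluripotency list (Tbx3, 52) and the Iroquois list (Irx5, 21). In the cell cycle list Cdkn2a (47), Cdkn1a (46) and Gadd45a (31) were bound. Gadd45a counted as unmarked by gene name, but its PLAGL1 peak overlapped an H3K4me3 peak. HOX peaks included those at Hoxa13 and Hoxa4 (30 each), with Hoxa10 and Hoxa5 at 21. The HOX list did not pass (adjusted p = 0.51, Fisher's exact test), nor did the lists with single bound genes.

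**Figure D1:**
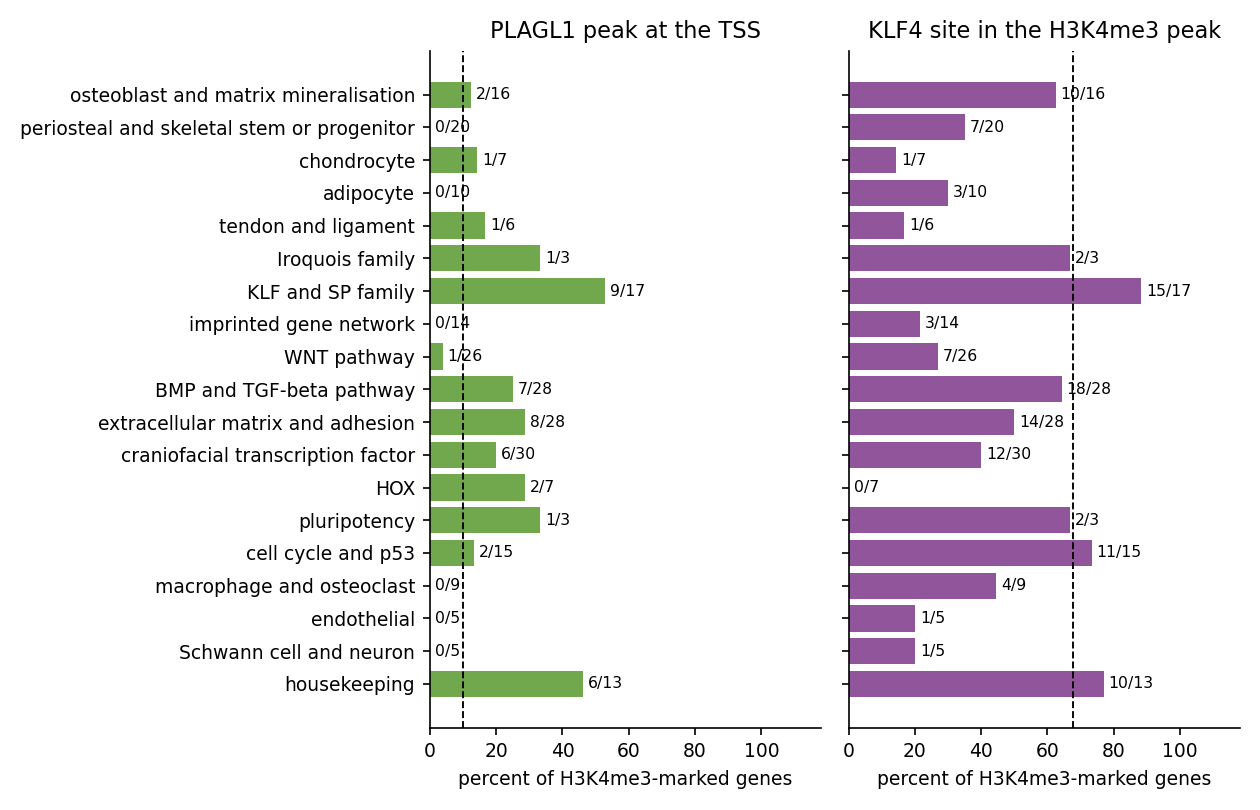
Percent of the H3K4me3-marked genes of each list that had a PLAGL1 peak within 3 kb of the TSS (left) or a KLF4 site inside the H3K4me3 peak (right), in percent on both horizontal axes. Labels give bound over marked genes, and dashed lines the share among all marked genes, 10.1% and 67.8%. The KLF and SP family has 9 of 17 genes with PLAGL1 and the WNT list 7 of 26 with KLF4.

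The 10 highest-scored PLAGL1 peaks were taken among peaks with a gene name that is not a predicted gene. Of these, 1 was in the promoter class and 6 overlapped an H3K4me3 peak. The peak with the top score of 402 lay at chr6:51155273-51155972, intergenic and 91268 bp from Mir148a. Others among the leading 10 were an intergenic peak near Lmx1a (268), the promoter of Mir7671 (263, chr11:53653887-53654974), an intergenic peak near Lrrc74a (233) and an intronic one in Bahcc1 (230). The list went on with 2 intergenic peaks near Ube2v1 (230 and 214), an intronic peak assigned to Mpeg1 (223), and intergenic peaks near Cep162 (208) and Irf2bp2 (204). By annotation class, 29.9% of PLAGL1 peaks were at a promoter (Wilson 95% interval 28.4% to 31.5%), 34.5% intronic and 28.2% intergenic. In the upper 50% of the score the promoter share was 33.4%. For H3K4me3 the promoter class held 24.4% (23.8% to 25.1%). That class is narrow, and counted within 3 kb of a TSS the shares were 46.7% for PLAGL1 and 80.2% for H3K4me3.

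PLAGL1 and KLF4 were found at many of the same places. Of the PLAGL1 peaks, 1686 (48.7%, interval 47.0% to 50.4%) overlapped an H3K4me3 peak, and among those in the promoter class 92.9% did. In 1000 random placements on the same chromosomes the mean was 0.99%, and the permutation p of 0.001 is the smallest these can give. KLF4 sites of the authors' deposited table overlapped 62.4% of PLAGL1 peaks (60.8% to 64.0%), against 0.79% at random. With H3K4me3 present 90.4% of PLAGL1 peaks overlapped a KLF4 site, and without it 35.9%. Per gene, KLF4 sites lay in the H3K4me3 peak of 92.7% of marked genes bound by PLAGL1 and of 65.0% of marked genes not bound (odds ratio 6.81, Fisher's exact test p = 9.3e-107). These intervals cover counting error only, peaks are not independent replicates, and placement over whole chromosomes includes stretches that reads cannot reach. Random placement also ignores that both lists favour marked promoters, and the test per gene was not stratified by the H3K4me3 score. A shared preference for strong promoters was therefore not separated from a link between PLAGL1 and KLF4.

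KLF4 was less frequent at marked genes of the WNT pathway than at other marked genes. Of the 26 marked WNT genes 7 had a KLF4 site in the H3K4me3 peak, Axin1, Fzd1, Fzd4, Tcf7l1 and Fzd2 among them, while Dkk3, Lrp5, Lrp6 and Ctnnb1 had none. The share among all marked genes was 67.8% (adjusted p = 0.00045, Fisher's exact test). Within strata of the H3K4me3 score the WNT deficit held, with adjusted p = 0.021 by the exact stratified test. Deficits by the unstratified Fisher's exact test were also found for HOX (0 of 7) and imprinted genes (3 of 14; both adjusted p = 0.0033), for periosteal (7 of 20) and craniofacial genes (12 of 30; both adjusted p = 0.012), for chondrocyte genes (1 of 7; adjusted p = 0.019), and for adipocyte (3 of 10) and tendon genes (1 of 6; both adjusted p = 0.040). All of these had adjusted p = 0.48 in the exact stratified test and were no longer called. Their stratified odds ratios still lay below 1, from 0 for HOX to 0.61 for the craniofacial list, against 0.235 for WNT, so these small lists leave open whether the strength of the mark accounts for the deficits. The remaining lists did not pass either test, with 15 of 17 KLF and SP genes, 10 of 16 osteoblast genes, 18 of 28 BMP and TGF-beta genes, 14 of 28 matrix genes, 11 of 15 cell cycle genes and 10 of 13 housekeeping genes. The same held for 4 of 9 macrophage genes, 2 of 3 Iroquois genes, 2 of 3 pluripotency genes, and 1 of 5 in both the endothelial and the Schwann cell list.

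The main comparison set KLF4 occupancy in control cells against Plagl1-deficient cells. In both groups this was tagged KLF4 supplied by lentivirus. An effect of Plagl1 on the level of the cells' own KLF4 was therefore not measured. KLF4 sites at named genes of the osteogenic and progenitor lists did not differ past the threshold, and few sites did anywhere: 10 of the 21130 sites in the authors' deposited table had an adjusted p under 0.05, of which 8 had a negative and 2 a positive log2 fold change. The table does not state which group is the numerator, so signs are given here without assigning a group. Of the 10 sites, 4 were at the end of chrY and 2 at the end of chrX, where the pseudoautosomal region lies, although only 25 of all sites in the authors' deposited table lay there. Outside these ends the authors' deposited table called a site 3342 bp from the Fam83h promoter peak (chr15:75885464-75886333, log2 fold change -0.76, approximate 95% interval -1.06 to -0.46, adjusted p = 0.0082) and a site 91877 bp from the Hmgcs1 promoter peak (chr13:120059184-120059705, -0.65, -0.93 to -0.38, adjusted p = 0.023). A site beside the ribosomal RNA gene copy Rn18s (chr17:40158422-40159644) had 0.26 (0.15 to 0.38, adjusted p = 0.048) in the authors' deposited table.

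The tenth, named after its values were seen, was near E230032D23Rik (chr7:143190309-143191106, 0.58, 0.33 to 0.83) in the authors' deposited table. At the sex chromosome ends, G530011O06Rik is the only gene name among the called sites, also given after the values were seen. Its chrY sites at 90755099-90755840 and 90822636-90824290 had log2 fold changes of -0.97 (-1.20 to -0.75) and -0.83 (-1.01 to -0.65), and its chrX site at 168776400-168777953 had -0.46 (-0.62 to -0.29), per the authors' deposited table. Without the sex chromosome ends and the ribosomal gene copy, adjustment over the remaining sites of the authors' deposited table left 1 call, at Fam83h (adjusted p = 0.049), while the site near Hmgcs1 and the one near E230032D23Rik were lost (both adjusted p = 0.085).

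At an unadjusted p under 0.05, 1364 sites of the authors' deposited table differed, 645 negative and 719 positive, against 1056.5 expected if no site changed. Across all sites the authors' deposited table had log2 fold changes with an SD of 0.23, and 95.9% of sites were within 0.5 of 0. The standard errors implied by the authors' deposited table had a median of 0.19, from 0.29 among the weakest to 0.12 among the strongest of 4 equal groups by mean signal. At the errors of the sites, simulated shifts of 0.5 in 200 sites were recovered in 20.1% of cases and shifts of 1 in 78.6%, so many moderate differences at single sites would be missed with these errors.

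**Figure D2:**
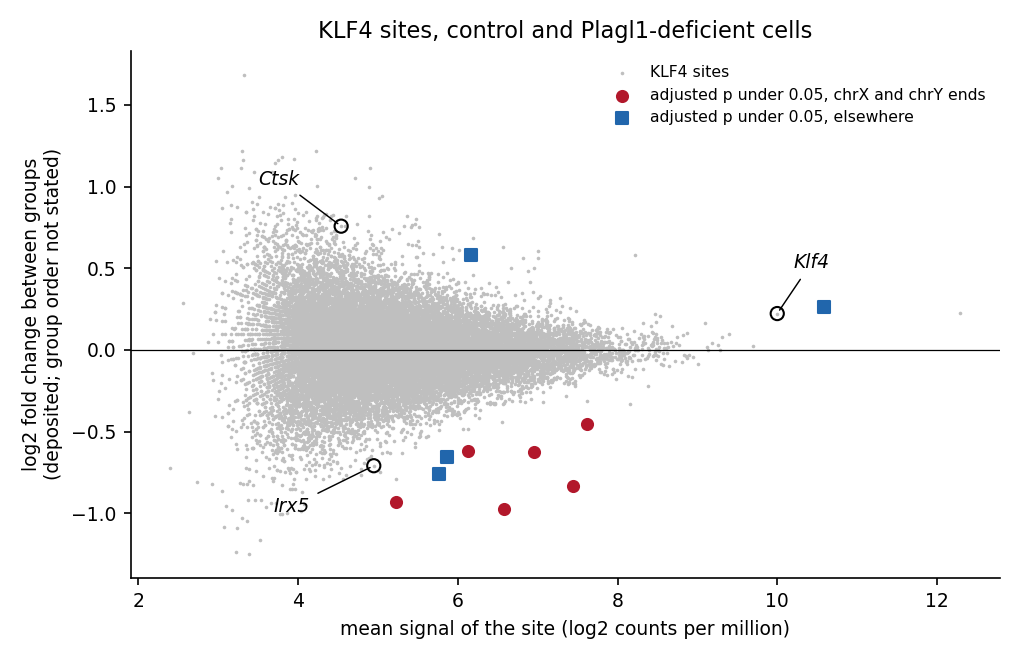
Log2 fold change of each KLF4 site between control and Plagl1-deficient cells (vertical axis, group order not stated) against its mean signal in log2 CPM (horizontal axis), from the authors' deposited table. Red circles are the 6 sites at the chrX and chrY ends with an adjusted p under 0.05, blue squares the 4 elsewhere, and open circles mark sites at Irx5 (-0.71), Klf4 (0.22) and Ctsk (0.76), which missed the threshold.

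At Irx5, KLF4, PLAGL1 and H3K4me3 coincided. A PLAGL1 peak at the Irx5 promoter (chr8:93084142-93084238, at -234 bp from the TSS) was among the weaker ones, with a score of 21 and rank 3041 of 3463. A second PLAGL1 peak with a score of 70 sat at the promoter of Crnde (chr8:93082570-93082937), the non-coding gene beside it, and another lay 148270 bp from the Irx5 TSS (score 30). The H3K4me3 peak at chr8:93082455-93085464 (score 350) spanned both promoters, and another was in intron 1 of Irx5 (score 76). The KLF4 site on the Irx5 promoter peak (chr8:93084096-93084363) had a log2 fold change of -0.71 (-1.10 to -0.32) with p = 0.00057 in the authors' deposited table. Its adjusted p there was 0.37, and adjusted over the list alone, the 5 Iroquois sites, it was 0.0028. The stronger KLF4 site on the Crnde side (chr8:93082440-93083533) had 0.01 (-0.17 to 0.19) in the authors' deposited table, and a site 70545 bp away had -0.11 (-0.59 to 0.38). Of 1193 KLF4 sites under a PLAGL1 peak within 3 kb of the TSS of a gene that is not a predicted gene, the Irx5 site had the second-lowest p in the authors' deposited table, after Cavin3 (-0.31, -0.48 to -0.15, adjusted p = 0.31).

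**Figure D3:**
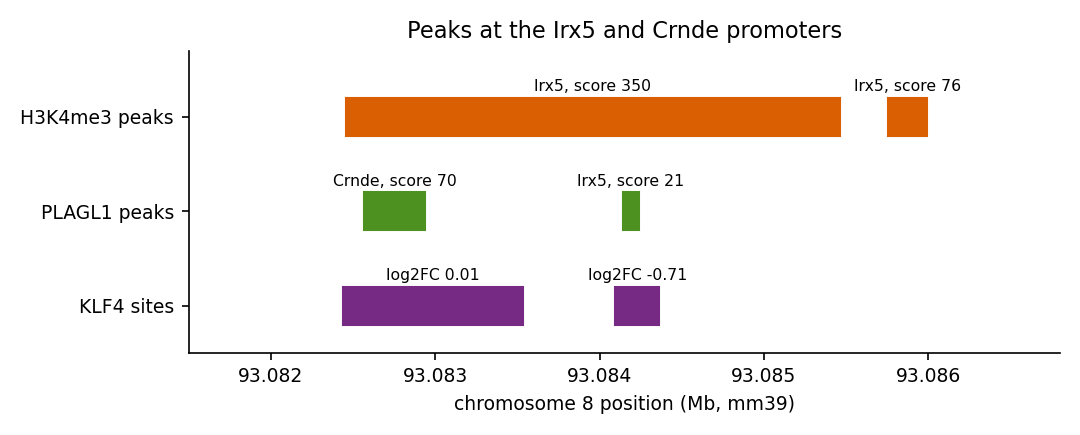
Positions on chromosome 8 (Mb, mm39) of H3K4me3 peaks, PLAGL1 peaks and KLF4 sites at the Irx5 and Crnde promoters, with peak scores and, for KLF4, the log2 fold change from the authors' deposited table. The KLF4 site at -0.71 lies on the Irx5 promoter PLAGL1 peak of score 21, and the site at 0.01 on the Crnde peak of score 70.

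At Klf4, the KLF4 site in the gene (chr4:55529729-55530975) had 0.22 (0.10 to 0.35), p = 0.00059 and an adjusted p of 0.37 in the authors' deposited table. Its signal ranked 3 of 21130 sites in the authors' deposited table, 30.2 times the median, and reads from the lentiviral Klf4 sequence cannot be separated from the gene's own. The other 4 sites named Klf4 had log2 fold changes from -0.43 to 0.06 in the authors' deposited table, all with intervals that include 0. PLAGL1 peaks named Klf4 lay at -118907 bp (score 47) and -581447 bp (score 49) from its TSS, and H3K4me3 peaks at the gene scored 791 and 53, with others at 408 and 230. No KLF4 site bears the name Plagl1.

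KLF4 sites of the fixed gene lists gave no calls: 0 sites in any of the 20 lists had an adjusted p under 0.05 by the authors' deposited table, and at an unadjusted p under 0.05 no list was enriched for either sign after adjustment over lists by Fisher's exact test. Adjusted over the list alone, 1 site passed in each of 5 lists by p-values from the authors' deposited table. These were Irx5 in the Iroquois list, Klf4 (0.22) in the KLF and SP list, Ctsk (0.76) in the periosteal list, Dcn (0.53) in the tendon list and Cdh5 (-0.39) in the endothelial list. No adjustment over the 20 lists was made here, so some of these may pass by chance. The same Dcn site is also in the imprinted list, where the smallest Benjamini-Hochberg value over the list alone was 0.088 and no site passed. Of genes with a PLAGL1 peak at the TSS, 1 had a called KLF4 site with a negative log2 fold change in the authors' deposited table: Hmgcs1, which encodes a cholesterol synthesis enzyme. Its PLAGL1 peak lay in the promoter (chr13:120151732-120152144, score 110), while the called KLF4 site was given to it only as the nearest promoter peak, 91877 bp away. That call did not hold without the sex chromosome ends and the ribosomal gene copy, and for a positive log2 fold change the count of such genes was 0 in the authors' deposited table.

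The remaining question was whether KLF4 sites that differed were sites of PLAGL1. Of the 8 called negative sites 2 (25%) overlapped a PLAGL1 peak, against 9.59% of uncalled sites in the authors' deposited table (Fisher's exact test p = 0.18, odds ratio 3.14). Both were the G530011O06Rik sites among the 6 negative calls at the chrX and chrY ends, and 0 of the 2 negative calls elsewhere, at Fam83h and Hmgcs1, overlapped one in the authors' deposited table. For H3K4me3 it was 2 of 8, against 48.5% of uncalled sites in the authors' deposited table (Fisher's exact test p = 0.29, odds ratio 0.35). Within strata of mean signal an exact stratified test gave p = 0.28 for PLAGL1, with H3K4me3 overlap as a further stratum, and 0.016 for H3K4me3, where overlap was the rarer outcome among called sites of the authors' deposited table. These tests count the 8 called sites as independent, although 6 of them cluster at the chrX and chrY ends. Both H3K4me3-overlapping sites were among those 6. Neither of the 2 called positive sites overlapped a peak of either kind.

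Among sites with an unadjusted p under 0.05 in the authors' deposited table, PLAGL1 peaks overlapped 80 of 645 negative sites (12.4%) and 37 of 719 positive sites (5.15%), against 9.67% of the other sites. Negative against positive sites gave an odds ratio of 2.61 (Fisher's exact test p = 1.7e-06), and 1.94 within strata of mean signal and H3K4me3 overlap (exact stratified p = 0.0014). Within the same strata the contrast lay with the positive sites, which were depleted of PLAGL1 against the other sites (odds ratio 0.587, exact stratified p = 0.0015). Negative sites did not differ from the other sites past the threshold there (odds ratio 1.20, exact stratified p = 0.16). H3K4me3 peaks overlapped 46.2% of negative and 28.9% of positive sites of the authors' deposited table (Fisher's exact test p = 4.6e-11), both below the 49.3% of the other sites. Unlike for PLAGL1, negative sites were depleted of H3K4me3 against the other sites within strata of mean signal (odds ratio 0.738, exact stratified p = 0.00034). These tests treat sites as independent and were chosen after the called sites were seen.

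**Figure D4:**
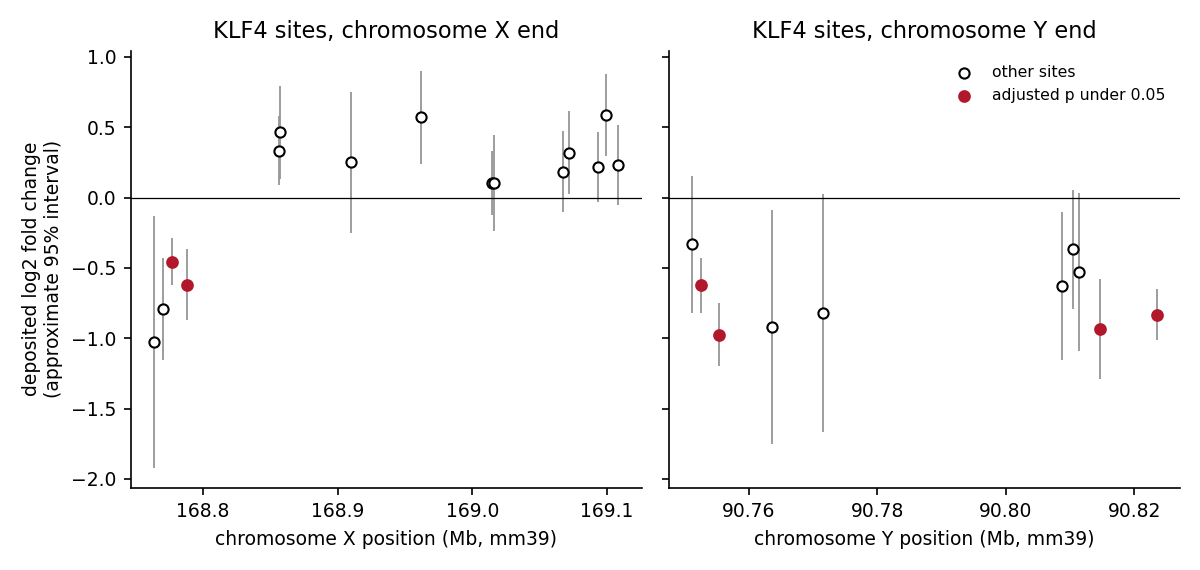
Log2 fold changes of the KLF4 sites at the ends of chromosomes X and Y (vertical axis) by position in Mb (horizontal axis), from the authors' deposited table; bars are approximate 95% intervals and filled points have an adjusted p under 0.05. All 10 chrY sites lie below 0, from -0.33 to -0.97, while on chrX 4 sites lie below 0 and the 11 sites beyond them lie above 0.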

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

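All tests in this part were chosen after the results were seen. The annotation of PLAGL1 peaks to repeats was used in no comparison of the report. It placed 97 PLAGL1 peaks (2.80%, 95% Wilson interval 2.30% to 3.41%) in RLTR17B_Mm, a long terminal repeat, against 7 of 16251 H3K4me3 peaks (0.043%). None of the 97 overlapped an H3K4me3 peak, and 41 (42.3%) overlapped a KLF4 site, against 35.9% of all PLAGL1 peaks without H3K4me3. The repeats IMPB_01 (14 peaks), (GT)n (14), (TG)n (12), B4A (11), (CA)n (8) and B3 (8) also had shares whose intervals lay above those of the H3K4me3 list. Repeats of any kind held 10.9% of PLAGL1 peaks, against 3.76% of H3K4me3 peaks, so an excess was not particular to those named. These shares were not matched on distance to the TSS. Within 3 kb of a TSS lay 46.7% of PLAGL1 peaks and 80.2% of H3K4me3 peaks.

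KLF4 calls were concentrated at the ends of chrX and chrY. Of the 15 chrX-end sites in the authors' deposited table, 5 had an interval above 0 and 4 an interval below 0. A pseudoautosomal segment has the same copy number in both sexes, so a different sex composition of the groups predicts no copy-number shift there. Intervals nevertheless lay off 0 there in both directions. How reads with several matches were handled is not given, so these sites do not decide on sex composition. Other effects of sex were not tested. For the chrY sites a different sex composition also stays open, and which of them lie in the pseudoautosomal region was not determined. All 10 lie at the end, so no site elsewhere on chrY was there to bear on it. The chrX sites away from the end had a median 0.022 above the autosomes (bootstrap interval -0.02 to 0.04) in the authors' deposited table. That sets no bound, since a small share of Y-bearing cells would leave chrX in place. A copy-number or haplotype difference over the chrY segment is a candidate explanation: the 10 sites of the authors' deposited table shared a shift of -0.74 within their errors, though narrowly (Cochran's Q p = 0.059). An effect of Plagl1 loss on KLF4 at these sites was not tested and stays open.

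The KLF4 site 270 bp from the Ctsk promoter peak had a log2 fold change of 0.76 (0.28 to 1.23, adjusted p = 0.52) and the next site, toward Ctss, 0.62 (0.02 to 1.22), in the authors' deposited table. The flanking sites at Arnt and Golph3l had 0.10 and -0.00 in the authors' deposited table. The mean of the pair, 0.69, stood at the 99.9th percentile of 833 neighbouring pairs of like signal at most 30 kb apart in the authors' deposited table, with 1 pair as high. Whether the Cre driver, present in the knockout cells only, carries extra copies of Ctsk sequence was not established here. If it does, they may account for this and would make positive values the knockout's. A change of KLF4 binding at Ctsk in these cells was not tested apart from such copies, and the pair was picked from many loci.

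KLF4 sites that overlapped a PLAGL1 peak had a mean log2 fold change below that of other sites by a small margin, -0.04 averaged over autosomes in the authors' deposited table (18 of 19 autosomes below 0, exact sign-flip p = 1.1e-05). The autosomes come from the same 6 libraries, so a difference between libraries moves them together, and these p-values do not measure the spread between samples. Within strata of both, 5 equal groups of mean signal and overlap with the mark, the difference was still -0.024 in the authors' deposited table. Its standard error was 0.0045, with 17 of 19 autosomes below 0 (exact sign-flip p = 0.00015). With strata of signal alone it was -0.028. Such strata leave differences in signal and in strength of the mark within them. Site abundance and the promoter mark therefore stay open as the whole cause. A difference in signal over background between the groups may also account for the lower mean: H3K4me3-marked sites without a PLAGL1 peak lay -0.039 from unmarked ones (standard error 0.0048, 18 of 19 autosomes, exact sign-flip p = 1.1e-05) in the authors' deposited table. Loss of PLAGL1 at its own sites stays open as a biological explanation, and no input library was used here to separate them.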

How the results depend on the processing

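Alternatives with an unadjusted p, without the chrX and chrY ends, or adjusted over the sites of 1 list were chosen after seeing the data. No paired analysis was possible because the deposited KLF4 table has no values per library; for the same reason other normalizations, filters, tests and pseudocounts, the replicate block and leaving out replicates were not run, splits of the 6 libraries could not be made, and the motif alternatives were not run for want of a genome. The calls of 8 negative and 2 positive KLF4 sites became 6 and 0 at an adjusted p under 0.01, 0 and 0 with an absolute log2 fold change of at least 1, and 645 and 719 at an unadjusted p under 0.05; without the chrX and chrY ends and the ribosomal gene copy they were 1 and 0, since the calls there were removed and fewer small p-values remained for the adjustment. The promoter share of PLAGL1 peaks went from 29.9% to 38.5% within 1 kb, 46.7% within 3 kb and 33.4% in the upper 50% of the score, and that of H3K4me3 peaks from 24.4% to 74.7%, 80.2% and 30.4%; the distance limits widen the class, and the cause for the score was not tested. PLAGL1 peaks overlapping H3K4me3 went from 48.7% to 46.2% with at least 50% of the peak covered, 54.7% in the upper 50% of the PLAGL1 score, and 31.6% with the upper 50% of H3K4me3 peaks, which are fewer. The share of negative KLF4 sites on PLAGL1 peaks kept its direction and stayed short of the threshold in the 4 alternatives set beforehand (25% to 50%); at an unadjusted p under 0.05 it was 12.4% and passed it (Fisher's exact test p = 0.026), with more sites tested, but not within strata of signal and H3K4me3 overlap (odds ratio 1.20, exact p = 0.16). For H3K4me3 the 4 alternatives (0% to 46.2%) kept direction and side, while strata of signal made the deficit pass for the called (odds ratio 0.147, exact p = 0.016) and the unadjusted negative sites (0.738, exact p = 0.00034). Both tests count sites as independent, although 6 of the 8 called negative sites lie at the chrX and chrY ends. The gene lists gave 0 in all 3 alternatives. Of alternatives set beforehand 12 moved the value and 10 left it the same; of those added later 4 moved it, 6 left it the same and 2 made it stronger. The Irx5 site's adjusted p of 0.37 was 0.0028 over the Iroquois list, 0.36 over the 1266 sites on PLAGL1 TSS peaks of all genes, predicted ones included, and 0.52 without the chromosome ends. The errors limit single sites: a median implied error of 0.19 calls for an absolute log2 fold change of 0.84. Depth per library is unknown, and its part in these errors was not tested.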

Other observations

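The comparisons with random lists here were chosen after the data were seen. The sites of several gene lists leaned to negative log2 fold changes in the authors' deposited table without any call. The percentiles are one-sided and not adjusted over lists. The random lists drew single sites, while several sites of a gene list can share a gene, so the percentiles may be too extreme. The median was -0.12 for 37 sites of craniofacial transcription factors, -0.09 for 57 sites of matrix genes, -0.07 for 64 sites of BMP and TGF-beta genes, -0.10 for 27 sites of osteoblast genes and -0.11 for 20 sites of periosteal progenitor genes in the authors' deposited table. Among 10000 random site lists matched on mean signal and H3K4me3 overlap, these medians stood at percentiles 0.31, 0.33, 0.44, 1.49 and 2.73. Of other lists, the endothelial one (6 sites, median -0.17 in the authors' deposited table) stood at percentile 2.92, the imprinted one (13 sites, -0.10) at 5.28 and the pluripotency one (5 sites, -0.19) at 5.93. The adipocyte list stood at 8.67, tendon at 9.12, KLF and SP at 12.5, WNT at 18.2, cell cycle at 20.5, Iroquois at 48.7 and Schwann cell at 59.6. The chondrocyte list had a median of 0.06 over 4 sites and the HOX list 0.14 over 3 sites in the authors' deposited table. The housekeeping list (29 sites, median 0.01 in the authors' deposited table) stood at percentile 64.1 and the macrophage and osteoclast list (15 sites, median 0.08) at 86.6. The sites with the lowest p in the matrix, BMP and osteoblast lists, per the authors' deposited table, were one 56169 bp from Col6a3 (-0.65, -1.06 to -0.24), one 37615 bp from Smad5 (-0.51, -0.88 to -0.13) and one on a PLAGL1 peak near Sp7 (-0.40, -0.71 to -0.10), the osteoblast transcription factor. Their adjusted p in the authors' deposited table was 0.52, 0.64 and 0.67. In the craniofacial list the lowest p was at a site 16709 bp from the Prrx2 promoter peak (-0.36, -0.64 to -0.09) in the authors' deposited table. In the periosteal list it was at the Ctsk site, which was positive (0.76, 0.28 to 1.23), against the lean of that list.

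Beside Irx5 and Cavin3, the sites under PLAGL1 TSS peaks with the lowest p in the authors' deposited table were at Mrgprf (-0.31), the cyclin-dependent kinase Cdk4 (0.30), the Notch target Hes1 (-0.40), Socs2 (-0.37), Dglucy (0.35), Mxra8 (-0.33), Tmem176b (-0.70) and Kctd11 (-0.29). Of these 8, 6 were negative in the authors' deposited table, and none had an adjusted p under 0.55. Beside the called chr7 site near E230032D23Rik another site was positive: 16574 bp from the Tnfrsf22 promoter peak the authors' deposited table gave 0.57 (0.27 to 0.86, adjusted p = 0.46), while the site in the Tnfrsf22 promoter peak between them had -0.30 (-0.81 to 0.21).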
